A study of Sus scrofa with 24 samples.

How the data were processed

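Total RNA of 24 samples from offspring of German Landrace gilts on a gestational high protein diet was, per the labels, isolated with TRI Reagent, treated with DNase and cleaned on RNeasy columns. Biotinylated cRNA was made from 0.5 µg of total RNA and hybridised to Affymetrix Porcine Genome arrays, 1 array per sample. The samples form 4 stages with 6 animals each, and per stage the offspring of 3 gilts were used. Mother, sex and array batch are not stated in the labels, so none could be a term of the model. Animals that share a mother are not independent, and the p-values, which treat all 6 as independent, are therefore too small by an unknown amount. Animal numbers follow the order of the samples within a stage and carry no pairing. The labels name liver and the series title muscle, and the tests assume neither.

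The authors used GCOS 1.1.1 and the deposited values are linear signal intensity, 1 value per probe set and array. Each array had been scaled: the mean without 2% of probe sets at each end was 498 to 499. Settings of the scaling and the probe summary are not given in the sources. The file holds 24118 probe sets without missing values. The 183 control probe sets were left out of the tests and 23935 were kept, with no filter on low values. Values were taken as log2 without an added constant. Gene symbols come from the platform annotation dated August 2016: 10069 tested probe sets have 1 symbol, 198 several and 13668 none, which gives 6765 genes, 2261 of them with more than 1 probe set. Of the single-symbol probe sets 9961 had a gene number found in the reference table of genes. No coordinates were used, as no genome build belongs to these arrays. Raw array images were not used.

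Background was set as the 95th percentile of the 17 Tag control probe sets over all arrays, a signal of 74.7. This choice was made after the data were seen, and 39.2% of tested probe sets had a mean under it. Where 1 stage mean lay under it, a fold is given as at least the ratio to this level, and where both did none is given.

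Differences were tested with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), by lmFit and eBayes on all 24 arrays with 4 stage means and 20 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. There were 4 comparisons: each stage with the one before it, and 188 dpn with 94 dpc. A second count asked for a change of at least 2-fold. An F test covered all stages. A probe set was highest or lowest at a stage when it passed against each other stage in that direction. As a null, 20 data sets without effect were simulated. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

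The 38 gene lists of pathways, cell types and technical signs, the comparisons, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists were chosen for liver, as the labels give it, and hold markers of muscle and other tissues. Each gene was represented by its brightest probe set. Lists were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 38 lists, and again with a correlation estimated from the residuals. The list medians use fitted differences of all members, those under background included. With the estimate 4, 0, 1 and 3 lists remained in the order of the comparisons. fry served as an alternative: its directional test asks whether the genes of a list move one way on balance and its mixed test whether they change at all, and neither compares a list with other genes. Members were counted with the adjustment over all probe sets and adjusted within the list alone. A further 10 lists of muscle biology were written after the data were seen and are not independent evidence of a direction.

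Genes were named by this rule: for each comparison the 8 largest rises and 8 largest falls among genes past the threshold whose stages did not overlap, and for each list discussed up to 4 members past the threshold with the largest difference and the brightest member. Which of the list members the rule allows are named was settled while writing, after their values were seen.

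Counts, named genes and the 38 lists were run with quantile normalization over all arrays, with each array centred on its median, without the dimmest 30% of probe sets and with each animal left out in turn. Counts and genes were also run with 16 or 64 added before the log2, with control probe sets kept, at an adjusted p of 0.01, with trend and robust settings of eBayes and with array weights. Changed probe sets per comparison and genes were run with only the 2 stages compared, and these counts with 1 probe set per gene. Genes and the 38 lists were run with the mean of all probe sets of a gene, and the lists with an estimated correlation and fry. The 10 added lists were run with an estimated correlation and in the 2 fits with fewer arrays named next, and their medians were also taken with quantile normalization and centred arrays. Ranges over alternatives cover those run for that result, without fry, which asks another question. After the data were seen, 2 more were added: without the 3 arrays of 1 dpn whose GAPDH ratio of 5′ to 3′ signal was under 0.5, and without the 3 arrays of 188 dpn with ALB over 10000. Both limits were set from the data. Each count was also compared with 100 regroupings of the arrays.

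The code was tested on simulated data with 50 changed probe sets at each of 4 sizes. At log2 sizes of 0.5, 1, 2 and 3, 0, 28, 46 and 74% were called for 1 dpn with 94 dpc and 0, 30, 48 and 80% for 28 dpn with 1 dpn. Among unchanged probe sets 4, 3, 1 and 0 were called in the 4 comparisons. A cell cycle list shifted by 1 was called and 0 other lists were. The bar set at first, over 50% recovered at a size of 2, was not met. It was replaced after this outcome was seen by a test of unbiased sizes, right directions, few false calls and power that rises with size.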

Results

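The series measured messenger RNA in 24 samples from offspring of German Landrace gilts fed a high protein diet in gestation. Each sample was hybridised to 1 Affymetrix Porcine Genome array, which reads transcripts by probe sets of short oligonucleotides. The samples form 4 stages of 6 animals each: 94 days post conception (94 dpc) and 1, 28 and 188 days post natum (dpn). The offspring of each stage came from 3 gilts, and the labels do not say which shared a mother. The sources conflict on the tissue, as the sample labels say liver and the series title names muscle. In all 24 arrays the median of a list of skeletal muscle genes lay between the 99.1 and 99.8 percentile of all probe sets, while that of a list of plasma protein genes of liver lay between the 21.1 and 97.6 percentile. In each array the muscle list median lay above the plasma protein list median, by at least 2.69 in log2. These values argue against liver as the main tissue of the arrays. The labels were not changed, and the tests assume no tissue. All 24 samples belong to 1 diet, so its effect is not analysed and the comparisons are between stages.

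Skeletal muscle genes were bright in every array, with list medians from 12621.5 to 62509.5 in scaled intensity units. Plasma protein genes differed between animals within stages. Their list median spanned 61.6 to 770 at 94 dpc, 66.9 to 705 at 1 dpn and 61.3 to 128 at 28 dpn. At 188 dpn their list median was 7488, 6053 and 873 in animals 1, 2 and 3 and 27.1, 33.2 and 87.8 in animals 4, 5 and 6. The albumin gene ALB, a plasma protein made in liver, stood at 56933, 45919 and 12421 in the former 3 arrays and at 123, 80.1 and 281 in the latter. The list median of complement genes was 1435, 1117 and 268 in animals 1, 2 and 3 of 188 dpn and 137, 102 and 86.3 in the others.

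**Figure D1:**
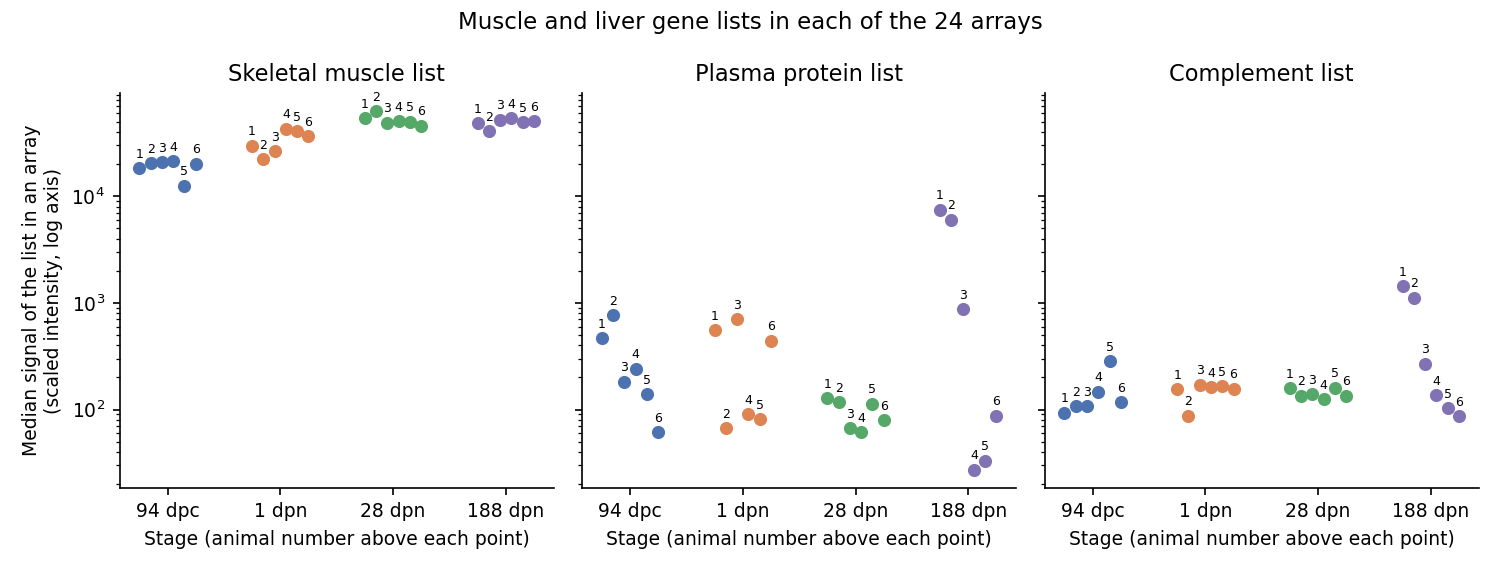
Median signal of 3 gene lists in each array (scaled intensity, log axis) against stage, with the animal number above each point. The muscle list stays above 12621 in all 24 arrays, while the plasma protein list spans 27.1 to 7488 among the 6 arrays of 188 dpn.

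Control transcripts differed in their 5′ signal between stages and between arrays of 1 dpn. The ratio of 5′ to 3′ signal of GAPDH, a glycolytic enzyme used as a control transcript, was 0.111, 0.296 and 0.254 in 1 dpn animals 1, 2 and 3 and 1.14, 0.841 and 1.04 in animals 4, 5 and 6. A different pair of GAPDH probe sets gave 0.424, 0.581 and 0.616 against 0.907, 0.996 and 0.946. The ratio of the elongation factor transcript EF1A was 0.135, 0.105 and 0.0963 in animals 1, 2 and 3 and at least 0.670 in the other 3. At the other stages it was 0.988 to 1.05 at 94 dpc, 0.638 to 0.696 at 28 dpn and 0.512 to 0.656 at 188 dpn, and mean actin ratios were 0.234, 0.0813, 0.178 and 0.164 in order of age. In 94 dpc animal 5 the muscle list median was 12621.5 against 18420 to 21214 in the other 5 fetuses, and the antigen presentation list median was 2171 against 532 to 807.

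**Figure D2:**
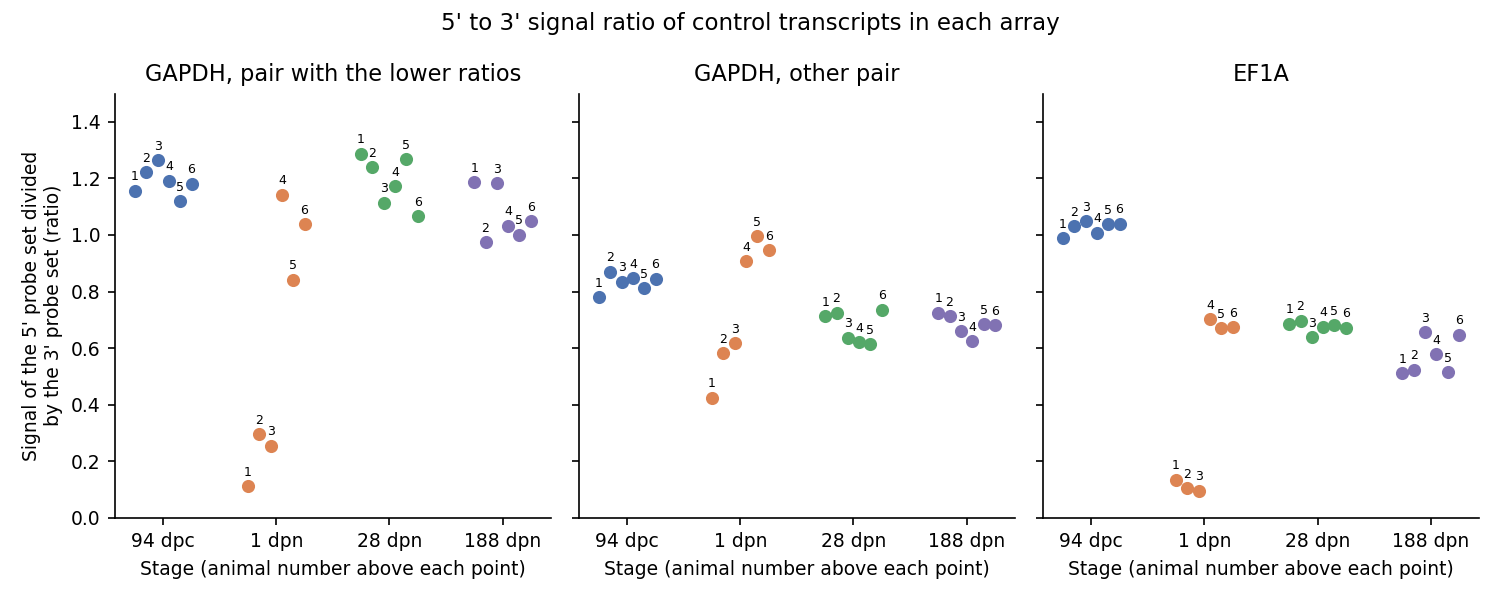
Ratio of 5′ to 3′ probe set signal of 2 GAPDH pairs and of EF1A in each array against stage, with the animal number above each point. Animals 1, 2 and 3 of 1 dpn have the lowest EF1A ratios, 0.0963 to 0.135.

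The comparison of 1 dpn with 94 dpc asks which transcripts differed between late gestation and the day after birth. CKMT2, the mitochondrial creatine kinase of muscle, rose from 1066 to 30675 (4.85 ± 0.22). PDK4, which inhibits the pyruvate dehydrogenase complex, rose from 370.3 to 6075 (4.04 ± 0.44), and ANGPTL4, an inhibitor of lipoprotein lipase, rose from 136 to 1789.6 (3.72 ± 0.26). TNNT2, the cardiac form of troponin T that is also found in developing muscle, fell from 3041 to 48.8 (at least 40.7-fold, SD 0.37 and 0.83), and MYL4, an embryonic myosin light chain, fell from 6286 to 237 (-4.73 ± 0.29). Here and below, levels are geometric means of 6 arrays per stage in scaled intensity, and brackets give the log2 difference ± SE, with n = 6 in each stage. Where 1 stage lay under the background level of 74.7, they give the smallest fold against that level and the SD of the log2 values in the earlier and the later stage.

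The other large rises were LOC100153598, a locus without a gene name in the annotation, from 647 to 21923 (5.08 ± 0.36), TRNP1 from 11.2 to 365 (at least 4.89-fold, SD 1.67 and 0.55) and CST6, a cystatin that inhibits cysteine proteases, from 27.8 to 667 (at least 8.93-fold, SD 1.91 and 0.29). TP53INP2, which takes part in autophagy, rose from 186 to 3035 (4.03 ± 0.28), and the small heat shock protein HSPB7 of muscle rose from 572 to 7787 (3.77 ± 0.21). Large falls included SPP1, which encodes osteopontin, from 7493 to 384 (-4.29 ± 0.63), the imprinted noncoding RNA MEG3 from 10694 to 604 (-4.15 ± 0.52), and the growth factor midkine, MDK, from 3242 to 222 (-3.87 ± 0.41). PPP4R1L fell from 156 to 8.99 (at least 2.09-fold, SD 0.38 and 1.48), SKA1, a protein of the spindle and kinetochore, fell from 98.9 to 7.11 (at least 1.32-fold, SD 0.44 and 1.32), and SHTN1 fell from 90.8 to 6.63 (at least 1.22-fold, SD 0.68 and 1.39). By the naming rule, here and below, the stages of these 16 genes did not overlap (adjusted p from 3.84e-12 to 3.22e-05).

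Oxidative phosphorylation genes rose together from 94 dpc to 1 dpn. In this list 33 of 34 measured genes rose and 0 fell (33 and 0 adjusted within the list alone). Its median was 1.28, or 1.43 relative to all probe sets (adjusted p = 2.19e-23; 0.0357 with an estimated correlation). NDUFA9, a subunit of complex I, rose from 3552 to 14604 (2.04 ± 0.18). UQCRB, of complex III, rose from 6593 to 26166 (1.99 ± 0.16), and ATP5A1, of the ATP synthase, rose from 20399.5 to 43142 (1.08 ± 0.17). Of the citric acid cycle, 16 of 18 genes rose and 0 fell (16 and 0 within the list). At the median the difference was 1.32, or 1.47 relative to all (adjusted p = 5.11e-10; 0.0548 with an estimated correlation). Its IDH2 rose from 7570.4 to 32876 (2.12 ± 0.14) and MDH2 rose from 6773 to 24671 (1.87 ± 0.16). Among genes of fatty acid oxidation, 17 of 27 genes rose and 0 fell (18 and 0 within the list). Their median stood at 1.19, or 1.34 relative to all (adjusted p = 1.32e-09; 0.00123 with an estimated correlation). ACADVL and ACADS, dehydrogenases of acyl-CoA esters, rose from 1999 to 17667 (3.14 ± 0.26) and from 366 to 1999.6 (2.45 ± 0.18). With quantile normalization the oxidative phosphorylation median was 0.81.

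Genes of gluconeogenesis and glycogen rose in part from 94 dpc to 1 dpn. Of this list, 9 of 13 genes rose and 0 fell (9 and 0 within the list), with a median of 1.37, or 1.53 relative to all (adjusted p = 4.72e-05; 0.00736 with an estimated correlation). The aminotransferase GOT1 rose from 1517 to 10242 (2.76 ± 0.18), the malate dehydrogenase MDH1 from 5274 to 27600.2 (2.39 ± 0.14) and the alanine aminotransferase GPT from 348 to 1289 (1.89 ± 0.25). Antioxidant genes rose as well: 16 of 23 genes rose and 0 fell (17 and 0 within the list). The members had a median of 0.83, or 0.98 relative to all (adjusted p = 2.63e-05; 0.00771 with an estimated correlation). SOD2, the mitochondrial superoxide dismutase, rose from 1151 to 5735 (2.32 ± 0.16) and GCLM, of glutathione synthesis, rose from 80.7 to 275 (1.77 ± 0.26). The antioxidant median was 0.50 with quantile normalization. Of the amino acid response list, 6 of 13 genes rose and 0 fell (6 and 0 within the list). The median difference was 0.65, or 0.80 relative to all (adjusted p = 0.0194; 0.252 with an estimated correlation). The transcription factor CEBPB rose from 1295 to 4532 (1.81 ± 0.31) and ATF4, the transcription factor of the response, rose from 6448 to 9698 (0.59 ± 0.15). The list lost its call with quantile normalization at a higher median of 0.94 (adjusted p = 0.0506) and without the 3 arrays of 1 dpn with low 5′ signal at 0.40 (adjusted p = 0.255), over a range of 0.00148 to 0.255 among all alternatives. ATF4 was at 0.16 with quantile normalization (adjusted p = 0.475), within 0.000124 to 0.475.

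Skeletal muscle genes moved mostly upward, an increase that depends on the scaling. Of the list, 17 of 25 genes rose and 1 fell (17 and 1 within the list), with a median of 0.78, or 0.94 relative to all (adjusted p = 4.65e-08; 0.252 with an estimated correlation), and with quantile normalization the median was 0.12 (adjusted p = 0.302, range 1.84e-10 to 0.302). ATP2A1, the calcium pump of fast fibres, rose from 1269 to 15147 (3.58 ± 0.22), the muscle glycogen phosphorylase PYGM rose from 6656 to 38244 (2.52 ± 0.16), and MYL3, a slow fibre light chain, rose from 4853 to 21491 (2.15 ± 0.24). MYL1, the brightest member, rose from 43476 to 65712 (0.60 ± 0.12) as deposited and turned to -0.07 with quantile normalization. Of the cytosolic ribosomal proteins, 34 of 58 genes rose and 0 fell (36 and 0 within the list), with a median of 0.46, or 0.61 relative to all (adjusted p = 1.32e-09; 0.393 with an estimated correlation), but the median turned to -0.15 with quantile normalization (adjusted p = 0.00168, range 4.24e-11 to 0.393). RPL27 rose from 27936 to 52032 (0.90 ± 0.14), and RPS20 rose from 41551 to 64900.3 (0.64 ± 0.13) as deposited and turned to -0.03 with quantile normalization. The muscle list median was 29908, 22349 and 26380.4 in the 3 arrays of 1 dpn with low 5′ signal and 43089, 40753 and 36779 in the other 3.

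Cell cycle genes fell by 1 dpn. Of the list, 0 of 28 genes rose and 20 fell (0 and 22 within the list). Its median was -2.02, or -1.87 relative to all (adjusted p = 8.16e-08; 0.0767 with an estimated correlation). UBE2C, which marks mitotic proteins for degradation, fell from 987 to 79.3 (-3.64 ± 0.66), the thymidylate synthase TYMS fell from 206 to 23.02 (at least 2.76-fold, SD 0.46 and 2.03), and the microtubule regulator STMN1 fell from 9836 to 2013 (-2.29 ± 0.18). Endothelial genes fell in part: 0 of 14 genes rose and 6 fell (0 and 8 within the list), with a median of -0.61, or -0.46 relative to all (adjusted p = 0.0316; 0.403 with an estimated correlation). The junction proteins CDH5 and PECAM1 fell from 3509 to 1462 (-1.26 ± 0.18) and from 4560.1 to 2139 (-1.09 ± 0.18), and the receptor TIE1 fell from 332 to 64.01 (at least 4.45-fold, SD 0.56 and 0.98). The endothelial call was lost with quantile normalization at a median of -0.32 (adjusted p = 0.101), with the mean of all probe sets of a gene at -0.53 (0.104), and without the 3 arrays of low 5′ signal at -0.50 (0.142). It was also lost when 1 array was left out, namely 94 dpc animal 4 at -0.58 (0.0621), 1 dpn animal 2 at -0.55 (0.0612) or 1 dpn animal 5 at -0.67 (0.0549), and its adjusted p ranged from 0.0106 to 0.403. Of the oncofetal list, genes high before birth in liver, 0 of 7 genes rose and 4 fell (0 and 5 within the list). Their median stood at -1.59, or -1.43 relative to all (adjusted p = 0.0316; 0.0774 with an estimated correlation). The imprinted genes PEG10, PEG3 and PLAGL1 fell from 17363 to 1696 (-3.36 ± 0.57), from 578 to 91.97 (-2.65 ± 0.38) and from 3330.2 to 1109 (-1.59 ± 0.27), and without 1 dpn animal 6 PEG10 was at -2.61. The oncofetal call was lost with the mean of all probe sets at -1.28 (0.104) and without 94 dpc animal 4 at -1.64 (0.0621), within 0.0151 to 0.104.

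In total 7409 of 23935 probe sets differed between 1 dpn and 94 dpc, 2429 higher and 4980 lower at 1 dpn (limma, adjusted p at most 0.05), of which 1295 and 3158 changed at least 2-fold. All 6 animals of 1 stage lay above all 6 of the other in 1248 genes past the threshold, which itself favours separation. The share of higher probe sets among the changed ones was 32.8% as deposited, 47.7% with quantile normalization and 59.2% with each array centred on its median, and the median over all probe sets was -0.15, 0.03 and 0.17. With the 3 arrays of low 5′ signal left out, 2029 were higher and 4122 lower, and 68.7% of the 7409 were called again in their direction. The 49 named genes that passed had adjusted p from 3.84e-12 to 0.00479. All 6 animals of 1 dpn lay on the same side of the mean of 94 dpc in each. The stages did not overlap in 47, in part by the naming rule here and below.

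The comparison of 28 dpn with 1 dpn asks what changed over the first 4 weeks after birth. MYH2, a fast myosin heavy chain, rose from 7653 to 69998 (3.19 ± 0.43), CAPN3, the calpain of muscle, rose from 359 to 4186 (3.54 ± 0.56), and GAMT, which makes creatine, rose from 492 to 4606 (3.23 ± 0.32). Without 1 dpn animal 3 CAPN3 was at 2.92. MYO5B, an unconventional myosin of vesicle transport, fell from 1079 to 131 (-3.04 ± 0.38), and the heat shock protein HSPB7 fell from 7787 to 1481 (-2.39 ± 0.21).

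MSS51 rose from 196 to 2003 (3.35 ± 0.26), the growth factor gene EGF from 372 to 3592 (3.27 ± 0.37) and AP2B1, an adaptor of clathrin coats, from 761 to 6921 (3.19 ± 0.24). LOC100510904 rose from 27.1 to 256 (at least 3.42-fold, SD 1.38 and 0.22) and MOSPD2 from 13.2 to 125 (at least 1.67-fold, SD 1.25 and 0.66). SDF2L1, of the endoplasmic reticulum, fell from 309 to 32.3 (at least 4.14-fold, SD 0.61 and 1.104), the adrenaline forming enzyme PNMT from 84.3 to 10.9 (at least 1.13-fold, SD 1.21 and 0.68) and OSBPL5 from 419.6 to 75.6 (-2.47 ± 0.47). TNFAIP6, which binds hyaluronan, fell from 124 to 8.69 (at least 1.66-fold, SD 1.02 and 1.77), and the thioesterase ACOT7 fell from 877 to 154 (-2.51 ± 0.57). ANKRD17 fell from 28.5 to 5.32 (both under the background level, SD 0.43 and 0.93), so no fold is given. Adjusted p of these 16 genes was 1.40e-08 to 0.00484. Without the 3 arrays of 1 dpn with low 5′ signal, TNFAIP6 was at 78.6 at 1 dpn (adjusted p = 0.0665) and ACOT7 differed by -1.80 ± 0.68 (0.0897). Over all alternatives adjusted p was 8.49e-05 to 0.0665 for TNFAIP6 and 2.18e-06 to 0.0897 for ACOT7.

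Cytosolic ribosomal protein genes fell in part between 1 dpn and 28 dpn. Of the list, 1 of 58 genes rose and 29 fell (1 and 32 within the list). Across members the median was -0.40 (adjusted p = 9.95e-10; 0.825 with an estimated correlation). RPL3 fell from 26327 to 9196 (-1.52 ± 0.14) and RPS25 fell from 36448 to 18616 (-0.97 ± 0.12), while RPS20, the brightest member, was at 64900.3 and 53516 (-0.28 ± 0.13) with adjusted p = 0.153. Quantile normalization gave a ribosomal median of -0.25. Genes of endoplasmic reticulum stress fell in part: 1 of 16 genes rose and 7 fell (1 and 8 within the list). The members had a median of -0.55 (adjusted p = 0.0332; 0.825 with an estimated correlation). The disulfide isomerase PDIA4 fell from 2930.3 to 1183 (-1.31 ± 0.19), and the transcription factor ATF4 was the member that rose, from 9698 to 27260.1 (1.49 ± 0.15). With the mean of all probe sets of the gene, PDIA4 was at -0.19 (adjusted p = 0.757) and ATF4 at 0.27 (0.478), with ranges of 2.10e-06 to 0.757 for PDIA4 and 2.10e-09 to 0.478 for ATF4. The list call was lost with quantile normalization at -0.52 (0.0553) and without 1 dpn animal 4 at -0.64 (0.0599), 1 dpn animal 6 at -0.42 (0.122) or 28 dpn animal 2 at -0.51 (0.0540), within 0.00197 to 0.825.

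Skeletal muscle genes rose in part from 1 dpn to 28 dpn: 8 of 25 genes rose and 0 fell (11 and 1 within the list), with a median of 0.28 (adjusted p = 0.00288; 0.825 with an estimated correlation). RYR1, the calcium release channel, rose from 5805 to 17103 (1.56 ± 0.17) and NEB, which encodes nebulin of the thin filament, rose from 20445 to 40906 (1.00 ± 0.14). The brightest member, MYL1, was at 65712 and 73796 (0.17 ± 0.12) with adjusted p = 0.384. Of the glycolysis and hypoxia list, 7 of 18 genes rose and 1 fell (8 and 1 within the list). Its median was 0.47 (adjusted p = 0.00288; 0.672 with an estimated correlation). The glycolytic enzyme genes GPI, TPI1 and PFKM rose from 10491 to 39932 (1.93 ± 0.19), from 17661 to 47249.8 (1.42 ± 0.21) and from 16719 to 44259 (1.40 ± 0.24). Of the cell cycle list, 9 of 28 genes rose and 0 fell (10 and 0 within the list). At the median the difference was 0.69 (adjusted p = 0.00288; 0.825 with an estimated correlation). The spindle checkpoint gene MAD2L1 rose from 142 to 479 (1.75 ± 0.22) and STMN1 rose from 2013 to 4637 (1.20 ± 0.18). The muscle list lost its call without the 3 arrays of 1 dpn with low 5′ signal, at a median of 0.17 (adjusted p = 0.0529, range 9.87e-05 to 0.825).

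Genes of antigen presentation rose in part from 1 dpn to 28 dpn: 8 of 19 genes rose and 2 fell (10 and 2 within the list). Their median stood at 1.03 (adjusted p = 0.00478; 0.825 with an estimated correlation). CD74, the invariant chain of class II molecules, rose from 125 to 702 (2.49 ± 0.33) and SLA-DRA, a class II chain, rose from 672 to 3721 (2.47 ± 0.46). The brightest probe set of B2M, the light chain of class I molecules, fell from 45345 to 32703 (-0.47 ± 0.14) (adjusted p = 0.0184), while the mean of all its probe sets gave 0.35 (adjusted p = 0.0178). Its fall was lost with quantile normalization at -0.32 (0.0780), with only the 2 stages fitted (0.103) and without the arrays of low 5′ signal at -0.24 ± 0.14 (0.309), within 0.00194 to 0.309. Interferon response genes rose in part: 4 of 18 genes rose and 0 fell (4 and 0 within the list), with a median of 1.22 (adjusted p = 0.0154; 0.825 with an estimated correlation). DDX58, a sensor of viral RNA, rose from 40.99 to 300.1 (at least 4.02-fold, SD 2.05 and 0.76) and IFI44L rose from 270.5 to 1007 (1.90 ± 0.51). Without the 3 arrays of low 5′ signal the antigen list median was 0.62 (adjusted p = 0.0856), that of the interferon list 0.88 (0.0946) and the difference of IFI44L 1.68 ± 0.65 (0.0973), whose range was 0.000313 to 0.0973. The interferon list also lost its call in fry's directional test (0.130) and without 1 dpn animal 5 at 1.09 (0.0509) or 28 dpn animal 3 at 0.99 (0.0550), within 0.000896 to 0.825, and the antigen list had a range of 0.000893 to 0.825.

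Between 28 dpn and 1 dpn 4945 probe sets differed, 2767 higher and 2178 lower at 28 dpn, of which 1695 and 926 changed at least 2-fold. No animal overlapped between stages in 845 genes past the threshold. Leaving out the 3 arrays of low 5′ signal, 1849 were higher and 1239 lower, and 50.5% of the 4945 were called again in their direction. With only the 2 stages fitted 3091 were called. The 36 named genes that passed had adjusted p from 1.40e-08 to 0.0184, with all 6 animals of 28 dpn on the same side of the mean of 1 dpn in each and no overlap in 35.

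The comparison of 188 dpn with 28 dpn asks what changed as the young animals grew older. FBXO32, a ubiquitin ligase subunit that is active in muscle wasting, rose from 611 to 6839 (3.49 ± 0.44), and UCHL1, a deubiquitinating enzyme, rose from 62.6 to 1265 (at least 16.9-fold, SD 1.38 and 0.48). ACTC1, the cardiac actin that is also made in developing muscle, fell from 29565 to 1149 (-4.68 ± 0.29), and CASQ2, the cardiac calsequestrin, fell from 519 to 45.5 (at least 6.95-fold, SD 0.46 and 1.15). MYBL2, a transcription factor of cycling cells, fell from 157 to 7.52 (at least 2.10-fold, SD 0.47 and 1.12), and RBP7, which binds retinol, fell from 404 to 13.1 (at least 5.41-fold, SD 0.31 and 1.08).

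TMEM140 rose from 87.99 to 1067 (3.60 ± 0.64), the RNA binding protein gene NANOS1 from 157 to 1403 (3.16 ± 0.40), and MRLN, which encodes a small regulator of the calcium pump, from 122 to 910.0 (2.90 ± 0.52). The immediate early gene FOS rose from 1144 to 8203 (2.84 ± 0.60). CYP3A29, a cytochrome P450, rose from 132 to 1664 (3.66 ± 0.96) and GNMT, a methyltransferase abundant in liver, rose from 17.2 to 240.4 (at least 3.22-fold, SD 1.41 and 1.71). Without 28 dpn animal 4 CYP3A29 was at 2.87. P3H4, of collagen modification, fell from 256 to 16.3 (at least 3.43-fold, SD 0.38 and 0.67), and SERHL2 fell from 4385 to 493 (-3.15 ± 0.27). PCLAF, which binds the replication clamp, fell from 209 to 24.96 (at least 2.80-fold, SD 0.27 and 1.71), and the cyclin CCNB2 fell from 120.2 to 14.8 (at least 1.61-fold, SD 0.17 and 1.81). These 16 genes had adjusted p from 2.86e-09 to 0.0115. Without the 3 arrays of 188 dpn with ALB over 10000, CYP3A29 had a difference of 3.48 ± 1.19 (adjusted p = 0.0804) and GNMT stood at 106 (0.0624), with adjusted p ranges of 9.21e-06 to 0.0804 for CYP3A29 and 0.000604 to 0.0624 for GNMT.

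Connective tissue matrix genes fell from 28 dpn to 188 dpn: 0 of 26 genes rose and 16 fell (1 and 18 within the list). The members had a median of -0.99, or -0.81 relative to all (adjusted p = 7.06e-07; 0.211 with an estimated correlation). POSTN, which encodes periostin, fell from 1379 to 163 (-3.08 ± 0.50). The collagen genes COL1A2 and COL4A2 fell from 1821 to 484 (-1.91 ± 0.35) and from 4839.5 to 1669.8 (-1.54 ± 0.20), and SPARC, which binds collagen, fell from 43220.1 to 24406 (-0.82 ± 0.15). Of the endothelial list, 0 of 14 genes rose and 9 fell (0 and 10 within the list). The median difference was -1.20, or -1.02 relative to all (adjusted p = 1.55e-05; 0.172 with an estimated correlation). PECAM1 fell from 3395 to 1062 (-1.68 ± 0.18) and CDH5 fell from 2255 to 705 (-1.68 ± 0.18). Of the cell cycle list, 0 of 28 genes rose and 15 fell (0 and 17 within the list). Its median was -1.25, or -1.07 relative to all (adjusted p = 3.11e-05; 0.211 with an estimated correlation). RRM2 and TOP2A, which serve DNA synthesis and its untangling, fell from 154 to 21.3 (at least 2.06-fold, SD 0.57 and 1.45) and from 273 to 40.1 (at least 3.66-fold, SD 0.27 and 0.97), and STMN1 fell from 4637 to 1811 (-1.36 ± 0.18).

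Genes of oxidative phosphorylation, the citric acid cycle and fatty acid oxidation fell in part from 28 dpn to 188 dpn. Of the oxidative phosphorylation list, 1 of 34 genes rose and 13 fell (1 and 22 within the list), with a median of -0.43, or -0.25 relative to all (adjusted p = 3.52e-05; 0.552 with an estimated correlation). COX7A2, of cytochrome oxidase, fell from 9375 to 4609 (-1.02 ± 0.15) and NDUFV1, of complex I, fell from 6613 to 3239 (-1.03 ± 0.20). ATP5A1, the brightest member, was at 48977 and 35899.8 (-0.45 ± 0.17) with adjusted p = 0.0777, and passed the threshold without 188 dpn animal 4 (adjusted p = 0.0361) and under 4 other alternatives. Of the citric acid cycle list, 0 of 18 genes rose and 7 fell (0 and 10 within the list). Their median stood at -0.49, or -0.31 relative to all (adjusted p = 0.00612; 0.552 with an estimated correlation). IDH3A fell from 2518 to 1415 (-0.83 ± 0.18) and MDH2 fell from 20548 to 12692 (-0.70 ± 0.16). Of the fatty acid oxidation list, 0 of 27 genes rose and 7 fell (2 and 9 within the list). Across members the median was -0.34, or -0.16 relative to all (adjusted p = 0.0185; 0.211 with an estimated correlation). ANGPTL4 fell from 1021 to 339 (-1.59 ± 0.26), and the beta oxidation enzyme genes ECI1 and HADHA fell from 9132 to 3819.6 (-1.26 ± 0.20) and from 6142 to 2997 (-1.04 ± 0.15). With arrays centred on their median the 3 list medians were -0.16, -0.22 and -0.07. If the 3 arrays of ALB over 10000 are left out, the citric acid cycle median was -0.35 (adjusted p = 0.164) and that of fatty acid oxidation, little moved, -0.33 (0.0579). NDUFV1, IDH3A and MDH2 then differed by -0.76 ± 0.24 (0.0518), -0.67 ± 0.23 (0.0757) and -0.53 ± 0.20 (0.112), with larger SE from fewer arrays. With centred arrays adjusted p was 0.0550 for the citric acid cycle list, IDH3A was at -0.56 (0.0526) and MDH2 at -0.43 (0.116), and with the mean of all probe sets IDH3A was at -0.82 (0.0814). Ranges over the alternatives were 7.81e-05 to 0.552 for the citric acid cycle list and 0.00204 to 0.211 for the fatty acid oxidation list. For genes they were 0.000144 to 0.0518 for NDUFV1, 0.0292 to 0.707 for ATP5A1, 0.000367 to 0.0814 for IDH3A and 0.000569 to 0.116 for MDH2.

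Interferon response and antigen presentation genes fell in part from 28 dpn to 188 dpn. Of the interferon response list, 0 of 18 genes rose and 6 fell (0 and 11 within the list). The members had a median of -1.59, or -1.41 relative to all (adjusted p = 0.00501; 0.598 with an estimated correlation). OAS1, which senses double-stranded RNA, fell from 994 to 218 (-2.19 ± 0.66) and IFIT3 fell from 708 to 177 (-2.00 ± 0.55). Of the antigen presentation list, 0 of 19 genes rose and 5 fell (0 and 11 within the list), with a median of -0.86, or -0.68 relative to all (adjusted p = 0.0138; 0.552 with an estimated correlation). SLA-6, a class I chain, fell from 802 to 287 (-1.48 ± 0.29) and CD74 fell from 702 to 314 (-1.16 ± 0.33). With quantile normalization OAS1 was at -1.98 (adjusted p = 0.0792), IFIT3 at -1.79 (0.0543) and CD74 at -1.01 (0.0613). Without the arrays of ALB over 10000 they were at -2.00 ± 0.85 (0.173), -2.04 ± 0.72 (0.0904) and -0.95 ± 0.41 (0.182), so the calls ended with larger SE while most of each difference stayed. Centring on the array median gave -1.92 (0.0523) for OAS1 and -0.89 (0.0591) for CD74, and the mean of all probe sets gave -0.72 (0.134) for SLA-6. OAS1 also lost its call when 1 of 28 dpn animals 2, 3 and 5 or 188 dpn animals 2 and 4 was left out, at -1.95 to -2.10 (0.0556 to 0.0705). Ranges over the alternatives were 0.00555 to 0.173 for OAS1, 0.00179 to 0.0904 for IFIT3, 0.00206 to 0.182 for CD74 and 9.63e-05 to 0.134 for SLA-6.

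Glucocorticoid and circadian genes rose in part from 28 dpn to 188 dpn: 3 of 12 genes rose and 0 fell (4 and 0 within the list). Its median was 0.37, or 0.55 relative to all (adjusted p = 0.00148; 0.0355 with an estimated correlation). The clock repressor CRY2 rose from 667 to 1873 (1.49 ± 0.15) (adjusted p = 8.72e-07) and the clock activator ARNTL rose from 50.9 to 166 (at least 2.22-fold, SD 1.55 and 0.53) (adjusted p = 0.0196). ARNTL lost its call with only the 2 stages fitted (0.0843) and without the arrays of ALB over 10000, at a level of 138 (0.186), within 0.00453 to 0.186, and was at 1.11 without 28 dpn animal 4. TSC22D3, the brightest member, was at 7241 and 8576 (0.24 ± 0.24) with adjusted p = 0.573.

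Genes typical of liver were higher at 188 dpn in a part of the animals. Of the plasma protein list, 1 of 28 genes rose and 0 fell (0 and 0 within the list). At the median the difference was 2.22, or 2.40 relative to all (adjusted p = 0.000112; 0.591 with an estimated correlation). The member that rose was ITIH3, a trypsin inhibitor heavy chain of plasma, from 56.8 to 294 (at least 3.94-fold, SD 1.30 and 2.29) (adjusted p = 0.0453), and APOA1, the brightest, was at 2222 and 2651 (0.25 ± 0.48) with adjusted p = 0.804. Of the complement list, 1 of 18 genes rose and 0 fell (0 and 0 within the list). Their median stood at 0.71, or 0.89 relative to all (adjusted p = 0.0206; 0.552 with an estimated correlation). The riser was the complement component C5, from 4.96 to 84.8 (at least 1.14-fold, SD 1.39 and 3.44) (adjusted p = 0.0358). Of the xenobiotic metabolism list, 3 of 29 genes rose and 3 fell (9 and 4 within the list), with a median of 0.78, or 0.96 relative to all (adjusted p = 0.0136; 0.552 with an estimated correlation). The carboxylesterase CES1 rose from 87.5 to 592 (2.76 ± 0.80) (adjusted p = 0.0227). Of the urea cycle, 1 of 5 genes rose and 0 fell (1 and 0 within the list), with a median of 1.34, or 1.52 relative to all (adjusted p = 0.0277; 0.552 with an estimated correlation), and the riser was the lyase ASL, from 178 to 499 (1.49 ± 0.37). Of the amino acid catabolism list, 4 of 22 genes rose and 0 fell (5 and 0 within the list). The members had a median of 0.48, or 0.66 relative to all (adjusted p = 0.0254; 0.552 with an estimated correlation). BCKDHB, of branched chain amino acid breakdown, rose from 1198 to 2525 (1.08 ± 0.26).

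These 5 lists moved with the arrays in which ALB was bright, animals 1, 2 and 3 of 188 dpn. Without these 3 arrays the plasma protein list median was -0.92 (adjusted p = 0.164), the complement list -0.22 (0.995), the xenobiotic metabolism list -0.26 (0.944), the urea cycle -0.49 (0.720) and amino acid catabolism -0.15 (0.944). ITIH3 and C5 then stood at 79.5 (0.772) and 12.3 (0.631) and CES1 differed by 0.69 ± 0.53 (0.529), while ASL kept most of its difference at 1.25 ± 0.47 (0.118) and lost its call with fewer arrays. Leaving out animal 1 or animal 2 of 188 dpn alone gave medians of 0.33 (0.117) and 0.42 (0.0770) for complement, 0.51 (0.105) and 0.60 (0.0770) for xenobiotic metabolism, 0.70 (0.111) and 1.01 (0.0770) for the urea cycle and 0.23 (0.140) and 0.26 (0.0770) for amino acid catabolism. The plasma protein median was 1.43, 1.48 and 2.83 without animal 1, 2 or 5. Without 188 dpn animal 4 CES1 was at 3.41, ITIH3 stood at 447 and, without animal 6, C5 at 161, which fell under background without animal 1 or 2. CES1 lost its call without 28 dpn animal 2 at 2.47 (0.0564), 188 dpn animal 1 at 2.08 (0.0569) or animal 2 at 2.21 (0.0653). C5 lost its call without 1 of 28 dpn animals 2, 4, 5 and 6 or 188 dpn animals 1, 2 and 3 (0.0640 to 0.0974). ITIH3 lost its call without 1 of 94 dpc animals 1, 3 and 5 or 1 dpn animals 2, 4 and 6. These arrays leave its difference as it is. The call was also lost without any 1 animal of 28 dpn or 1 of 188 dpn animals 1, 2 and 3 (all 0.0502 to 0.122). With arrays centred on their median the calls of complement, xenobiotic metabolism, urea cycle and amino acid catabolism were lost at larger medians, 0.98 (0.149), 1.05 (0.133), 1.61 (0.133) and 0.75 (0.139). In fry's directional test adjusted p was 0.209, 0.207, 0.209 and 0.169 for the plasma, complement, xenobiotic and catabolism lists, and 0.260 for the last without the dimmest 30% of probe sets. With only the 2 stages fitted it was 0.131 for ITIH3, 0.0660 for C5 and 0.0904 for CES1, and without the arrays of low 5′ signal 0.0553 for ITIH3. Ranges over all alternatives were 2.76e-07 to 0.591 for plasma proteins, 0.00205 to 0.995 for complement, 0.00106 to 0.944 for xenobiotic metabolism, 0.00993 to 0.720 for the urea cycle and 0.00281 to 0.944 for amino acid catabolism. For genes they were 0.00776 to 0.772 for ITIH3, 0.00774 to 0.631 for C5, 0.00286 to 0.529 for CES1 and 8.20e-05 to 0.118 for ASL.

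Between 188 dpn and 28 dpn 3498 probe sets differed, 987 higher and 2511 lower at 188 dpn, of which 421 and 1421 changed at least 2-fold. The stages did not overlap in 988 genes past the threshold. The share of higher probe sets was 28.2% as deposited, 42.0% with quantile normalization and 62.9% with centred arrays. The median over all probe sets was -0.18, 0.01 and 0.09. On leaving out the 3 arrays of ALB over 10000, 509 were higher and 1563 lower, and 53.9% of the 3498 were called again in their direction. Among the 46 named genes that passed, with adjusted p from 2.86e-09 to 0.0453, all 6 animals of 188 dpn lay on the same side of the mean of 28 dpn in 43 and 5 of 6 did in CES1, ITIH3 and C5. The stages did not overlap in 40 of them.

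The comparison of 188 dpn with 94 dpc asks what differed between the last fetal stage and the oldest animals. FBP2, the fructose bisphosphatase of muscle, rose from 717 to 19198 (4.74 ± 0.31) and PDK4 rose from 370.3 to 13586 (5.20 ± 0.44). PEG10, an imprinted gene, fell from 17363 to 142 (-6.94 ± 0.57), the matrix gene POSTN fell from 12760.1 to 163 (-6.29 ± 0.50) and the imprinted RNA MEG3 fell from 10694 to 216 (-5.63 ± 0.52). MYBL2 fell from 587 to 7.52 (at least 7.86-fold, SD 0.16 and 1.12) and IGSF1, an immunoglobulin superfamily member, fell from 4395 to 71.4 (at least 58.9-fold, SD 0.31 and 0.32).

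**Figure D3:**
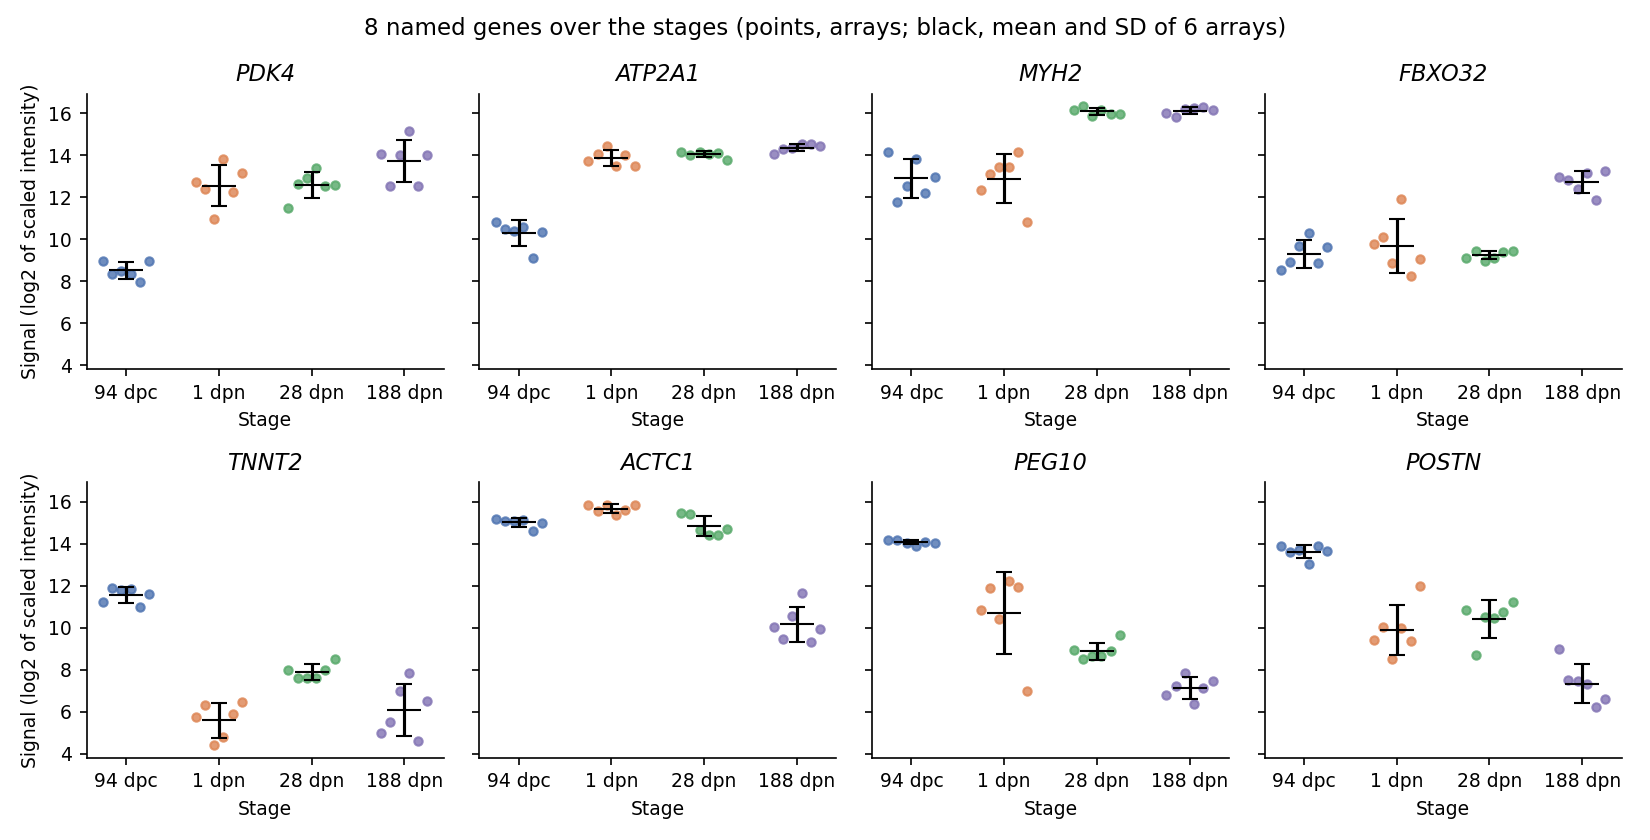
Signal of 8 named genes (log2 of scaled intensity) against stage; points are arrays and black marks the mean and SD of 6 arrays. PDK4 rises from 370.3 at 94 dpc to 13586 at 188 dpn, and PEG10 falls from 17363 to 142.

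CST6 rose from 27.8 to 2199 (at least 29.5-fold, SD 1.91 and 0.22), TRNP1 from 11.2 to 599 (at least 8.03-fold, SD 1.67 and 0.29) and the antimicrobial peptide gene DEFB1 from 17.2 to 531 (at least 7.11-fold, SD 1.26 and 0.40). LOC100153598 rose from 647 to 27630.1 (5.42 ± 0.36) in its brightest probe set, while its other probe set passed the threshold in the opposite direction. C4BPA, which binds complement component C4b, rose from 87.9 to 3954 (5.49 ± 0.81) and CYP3A29 from 8.80 to 1664 (at least 22.3-fold, SD 2.30 and 1.16). Without 94 dpc animal 5 C4BPA stood at 44.4 there, under background. LOC396711, also without a gene name, fell from 28644 to 168 (-7.41 ± 0.56), CASQ2 fell from 2210.1 to 45.5 (at least 29.6-fold, SD 0.33 and 1.15) and P3H4 fell from 738 to 16.3 (at least 9.89-fold, SD 0.42 and 0.67). These 16 genes had adjusted p from 8.07e-14 to 8.79e-06.

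Skeletal muscle genes rose from 94 dpc to 188 dpn: 24 of 25 genes rose and 1 fell (24 and 1 within the list). The median difference was 1.26, or 1.55 relative to all (adjusted p = 1.23e-11; 0.126 with an estimated correlation). ATP2A1 rose from 1269 to 21261 (4.07 ± 0.22), MYH2 from 7754 to 71827 (3.21 ± 0.43) and PYGM from 6656 to 49588 (2.90 ± 0.16). MYOD1, a transcription factor of muscle precursor cells, was the member that fell, from 1831 to 266 (-2.78 ± 0.22). The list median was 0.74 with quantile normalization. MYL1 rose from 43476 to 70408 (0.70 ± 0.12) as deposited and was at 0.04 with quantile normalization (adjusted p = 0.766, range 8.67e-08 to 0.766). Of the gluconeogenesis and glycogen list, 7 of 13 genes rose and 0 fell (7 and 0 within the list). Its median was 1.12, or 1.41 relative to all (adjusted p = 0.000387; 0.0351 with an estimated correlation). SLC37A4, a glucose 6-phosphate transporter, rose from 452 to 6918 (3.94 ± 0.22) and PGM1, a phosphoglucomutase, rose from 6809 to 54858 (3.01 ± 0.25).

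Genes of oxidative phosphorylation and the citric acid cycle were higher at 188 dpn than at 94 dpc. Of the oxidative phosphorylation list, 29 of 34 genes rose and 2 fell (30 and 2 within the list), with a median of 0.72, or 1.01 relative to all (adjusted p = 6.92e-09; 0.210 with an estimated correlation), and with quantile normalization it was 0.25 with adjusted p = 0.0618 (range 2.38e-10 to 0.210). SDHC, of complex II, rose from 1830.0 to 7247 (1.99 ± 0.18) and ATP5J, of the ATP synthase, rose from 2132 to 7311 (1.78 ± 0.15), while COX6A1, a cytochrome oxidase subunit, fell from 6015 to 2139.7 (-1.49 ± 0.23). Of the citric acid cycle list, 15 of 18 genes rose and 2 fell (15 and 2 within the list), with a median of 1.14, or 1.43 relative to all (adjusted p = 6.52e-06; 0.154 with an estimated correlation). The median was 0.73 with quantile normalization. SUCLA2 rose from 1016 to 5435 (2.42 ± 0.27) and IDH2 from 7570.4 to 23492 (1.63 ± 0.14). Of the fatty acid oxidation list, 13 of 27 genes rose and 0 fell (13 and 0 within the list), with a median of 0.54, or 0.83 relative to all (adjusted p = 0.000323; 0.0411 with an estimated correlation), and ACADS rose from 366 to 1377 (1.91 ± 0.18). Of the antioxidant list, 14 of 23 genes rose and 5 fell (14 and 7 within the list), with a median of 0.93, or 1.22 relative to all (adjusted p = 0.00637; 0.0915 with an estimated correlation), and it was 0.55 with quantile normalization (adjusted p = 0.0603, range 0.00309 to 0.0915). SOD2 rose from 1151 to 9449 (3.04 ± 0.16) and the plasma glutathione peroxidase GPX3 rose from 128 to 965 (2.92 ± 0.43).

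Matrix, vessel and cell cycle genes were lower at 188 dpn than at 94 dpc. Of the matrix list, 1 of 26 genes rose and 22 fell (1 and 23 within the list). Their median stood at -1.64, or -1.35 relative to all (adjusted p = 2.99e-06; 0.154 with an estimated correlation). COL1A2 fell from 4418 to 484 (-3.19 ± 0.35) and COL5A1 from 6198 to 832 (-2.90 ± 0.22). Of the endothelial list, 1 of 14 genes rose and 12 fell (1 and 13 within the list), with a median of -1.69, or -1.40 relative to all (adjusted p = 0.000741; 0.154 with an estimated correlation), and CDH5 and PECAM1 fell from 3509 to 705 (-2.31 ± 0.18) and from 4560.1 to 1062 (-2.10 ± 0.18). Of the cell cycle list, 1 of 28 genes rose and 24 fell (1 and 25 within the list). Across members the median was -2.29, or -2.00 relative to all (adjusted p = 6.52e-06; 0.143 with an estimated correlation). CDC20, which activates the mitotic ubiquitin ligase, fell from 394 to 23.97 (at least 5.28-fold, SD 0.35 and 1.02) and CENPF, a kinetochore protein, fell from 308 to 18.96 (at least 4.13-fold, SD 0.60 and 1.00). Of the oncofetal list, 0 of 7 genes rose and 6 fell (0 and 6 within the list). The members had a median of -3.76, or -3.47 relative to all (adjusted p = 0.00211; 0.0351 with an estimated correlation). PLAGL1 fell from 3330.2 to 149 (-4.48 ± 0.27) and the growth factor gene IGF2 fell from 11018 to 815 (-3.76 ± 0.37).

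Glucocorticoid and circadian genes rose in part from 94 dpc to 188 dpn: 5 of 12 genes rose and 0 fell (5 and 0 within the list), with a median of 0.40, or 0.69 relative to all (adjusted p = 0.0303; 0.0915 with an estimated correlation). FKBP5, a co-chaperone induced by glucocorticoids, rose from 111 to 1234 (3.47 ± 0.44) and CRY2 rose from 489 to 1873 (1.94 ± 0.15). The list lost its call with arrays centred on their median at a larger 0.94 (adjusted p = 0.113), without the arrays of ALB over 10000 at a larger 0.54 (0.0767) and without the arrays of low 5′ signal at an unmoved 0.40 (0.0589), within 0.0160 to 0.113. Of the amino acid catabolism list, 5 of 22 genes rose and 1 fell (4 and 1 within the list). Its median was 0.91, or 1.20 relative to all (adjusted p = 0.0491; 0.577 with an estimated correlation). BCKDHB rose from 341 to 2525 (2.89 ± 0.26), and CDO1, which oxidises cysteine, fell from 3321 to 798 (-2.06 ± 0.28). This call was lost when 1 of 94 dpc animals 3, 4, 5 and 6, 1 dpn animals 1, 2, 4, 5 and 6 or 188 dpn animals 1 and 2 was left out, at 0.54 to 0.91 (0.0501 to 0.141). It was also lost without the arrays of ALB over 10000, with a median of -0.06 (adjusted p = 0.612), without those of low 5′ signal at 0.91 (0.0589), with centred arrays at 1.44 (0.256), without the dimmest 30% of probe sets at 0.75 (0.133) and with the mean of all probe sets at 0.97 (0.0529), within 0.0123 to 0.612.

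Between 188 dpn and 94 dpc 9548 probe sets differed, 2990 higher and 6558 lower at 188 dpn, of which 1833 and 4873 changed at least 2-fold. The stages did not overlap in 2551 genes past the threshold. The share of higher probe sets was 31.3% as deposited, 48.9% with quantile normalization and 60.8% with centred arrays. The median over all probe sets was -0.29, 0.05 and 0.25. Once the 3 arrays of ALB over 10000 were left out, 2496 were higher and 5430 lower, and 78.8% of the 9548 were called again in their direction. In the 49 named genes that passed the stages did not overlap, with adjusted p from 8.07e-14 to 8.21e-05.

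**Figure D4:**
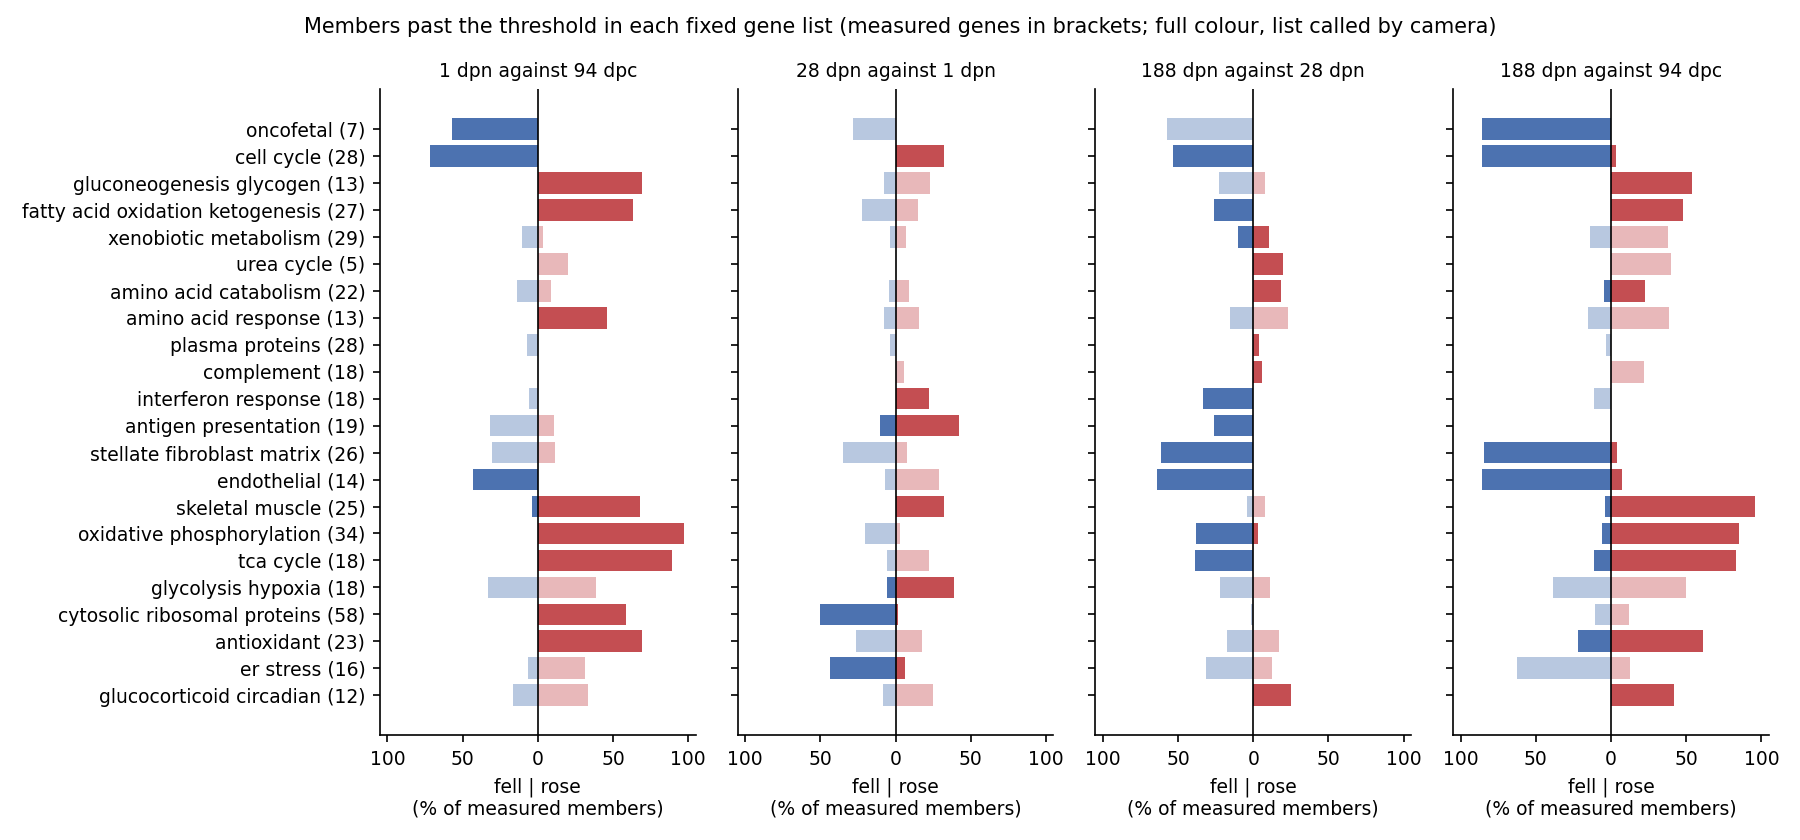
Percent of measured members that rose (right) or fell (left) in each of the 22 lists called in at least 1 comparison, with full colour where the list was called. In the oxidative phosphorylation list 33 of 34 genes rose from 94 dpc to 1 dpn; the rise of the ribosomal list in that comparison reverses with quantile normalization.

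Across the 4 stages 12517 probe sets (52.3%) differed in limma's F test. Probe sets above each other stage numbered 2105 at 94 dpc, 614 at 1 dpn, 58 at 28 dpn and 661 at 188 dpn, and those below each other stage 999, 1119, 36 and 1725. Simulated data with no effect gave at most 0 at any stage. Highest at 1 dpn were 23 of 58 ribosomal proteins and 6 of 34 oxidative phosphorylation genes. Of 28 cell cycle genes 10 were highest at 94 dpc. With quantile normalization 0 ribosomal proteins were highest at 1 dpn and 11 at 94 dpc, and the other counts were 4 and 7. Median correlations between arrays were 0.907, 0.855, 0.900 and 0.890 within stages in order of age and 0.842 between stages.

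Of the 38 gene lists, 16 passed in no comparison. The number called, 11, 7, 14 and 12 in the order above, was reached in 34, 13, 10 and 51 of 100 random regroupings. The lowest adjusted p of each over the 4 comparisons was 0.0533 for immediate early genes, 0.0627 for housekeeping genes, 0.108 for macrophages, 0.120 for the acute phase, 0.165 for bile acids, 0.170 for DNA methylation and chromatin and 0.251 for erythroid genes. It was 0.344 for the growth hormone axis, 0.370 for exocrine pancreas, 0.468 for granulocytes, 0.473 for lipogenesis, 0.612 for metallothioneins and iron, 0.619 for lymphocytes, 0.665 for cholesterol synthesis, 0.681 for hepatocyte transcription factors and 0.705 for cholangiocytes.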

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

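Of the tests in this part, the 3 on plasma protein genes, the stage test of the EF1A ratio and the centring of arrays were chosen after the result was seen, and those on degraded RNA, on arrays with low 5′ signal, on bright probe sets, on background and on regroupings before their results. The stage test replaced one on GAPDH whose bound was changed once after its outcome was seen and set back, and that on muscle genes replaced one that compared different probe sets.

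Plasma protein genes were bright in 3 of the 6 arrays of 188 dpn. A whole array of liver in place of muscle is argued against. The lowest muscle list median of the 3 differed by only -0.311 in log2 from the median of the other 3 (41023 against 49224 to 53664). A change with stage shared by all animals is argued against by the lowest plasma protein median of 188 dpn, 27.1, which lies under the median of 28 dpn, 94.8. RNA from liver may have entered these arrays. Of 4 liver lists, 3 had their highest median at 188 dpn in the array with the brightest plasma protein list. The xenobiotic metabolism list stood at 924 there and 925 in animal 2. RNA from liver cannot be told apart from a difference between these animals, such as their mothers, which was not tested. The liver transcript AHSG also ranged from 679 to 22599 at 94 dpc. The pancreas transcript CLPS was 2255 and 783 in 1 dpn animals 3 and 1, 695 in 188 dpn animal 3, elsewhere at most 121. Its source was not tested.

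Low 5′ signal of GAPDH was found in 3 arrays of 1 dpn. Degraded RNA may be the cause. In all 3 the EF1A ratio, at most 0.135, lay under that of each other array of 1 dpn, at least 0.670. A change with stage shared by the animals is argued against, since the gap of 0.535 in the EF1A ratio between these and the other 3 arrays of 1 dpn is wider than the widest range within another stage, 0.144. The highest GAPDH ratio of 1 dpn, 1.14, did not decide it, between the lowest of the other 18 arrays, 0.975, and their median, 1.18. Differences between mothers were not tested. The EF1A ratio also differed without overlap between 94 dpc and each later stage, and RNA integrity cannot be separated from stage there. With the other 3 arrays alone, 90.5% of calls for 1 dpn with 94 dpc kept sign and at least 50% of their difference. For 28 dpn with 1 dpn 87.1% did. The other 3 also made the calls, so this cannot decide if low 5′ arrays drive the counts.

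More probe sets fell than rose from 94 dpc to 188 dpn. The scaling of each array to a common trimmed mean stays open: 60.8% of calls were higher when each array was centred on its median, but centring itself sets this balance. Bright probe sets could be its source, as the brightest 10 percent held a median of 58.7% of the trimmed signal at 188 dpn (57.6 to 59.5) and 48.4% at 94 dpc (45.4 to 50.2). Fewer transcripts above background remain open: 60.5% of probe sets lay above the brightest tag control at 188 dpn (58.0 to 65.4) and 65.3% at 94 dpc (60.8 to 77.4), and the ranges overlap. A true fall in most transcripts stays open, and total RNA per cell was not measured.

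Regrouping single arrays at random excludes chance for the counts of probe sets only if the arrays are independent. The 6 animals of a stage come from 3 gilts, so differences between litters are not in these regroupings and are not excluded. Of 100 splits, 1, the real one, gave as many in each comparison. The real counts and the highest of other splits were 7409 and 4354, 4945 and 2015, 3498 and 57, and 9548 and 4867, and with a 2-fold minimum 4453 and 2591, 2621 and 1156, 1842 and 50, and 6706 and 3356. For the F test they were 12517 and 1289, for probe sets highest at 1 stage 3438 and 1, and for those lowest 3879 and 1. Chance is not excluded for the number of lists called: 34, 13, 10 and 51 of 100 splits gave as many as the real 11, 7, 14 and 12, with up to 15, 9, 16 and 21. Splits that mix the stages unequally keep part of the real difference. They therefore cannot show how many lists chance alone would give.

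In 61 of 656 groups of 6 arrays the highest or lowest array stood far from the other 5, where chance gives about 1 in 20. Values in brackets are the range of the other 5 arrays of the stage. Array 94 dpc animal 5 had the skeletal muscle list at 12622 (18420.0 to 21214), the oxidative phosphorylation list at 5259.9 (7237 to 8448), the ribosomal protein list at 23630.4 (31414 to 35236) and the antigen presentation list at 2171 (532 to 807). Of its genes, it had SPP1 at 20499 (4109.6 to 7002), SHTN1 at 229.6 (64.7 to 95.98), GPT at 174 (356 to 441) and TIE1 at 153 (338 to 426). It further held ATP2A1 at 557 (1329 to 1809.8), UQCRB at 5269 (6662 to 7397), ATP5A1 at 15090.5 (20549 to 22989.7) and RPL27 at 20273 (27553 to 33021). The same array had RPS20 at 30906 (42082 to 45853), DDX58 at 1412 (102 to 196), CD74 at 1339.9 (281 to 381) and SLA-DRA at 7988 (1259 to 1694). Also apart in it were B2M at 25964 (33289 to 37528), RYR1 at 3703 (6493 to 7521), TPI1 at 5523 (7873 to 9550.4) and ACTC1 at 25506 (32739 to 37892). To these come SLA-6 at 871 (299 to 425), NDUFV1 at 1756 (2657 to 3268) and FKBP5 at 329 (72.9 to 103). CST6 at 385 (9.38 to 22.4), MSTN at 74.7 (211 to 388) and POSTN at 8556 (12739 to 15237) stood apart in 94 dpc animal 4. TP53INP2 at 76.1 (175 to 261) stood apart in 94 dpc animal 6. FOS at 1348 (256 to 461) and P3H4 at 59.3 (359 to 876) stood apart in 1 dpn animal 1. The complement list at 87.5 (155 to 172) stood apart in 1 dpn animal 2. DDX58 at 2.30 (58.3 to 91.9) stood apart in 1 dpn animal 3. UCHL1 at 18.96 (269 to 1203), RRM2 at 6.13 (82.5 to 125), TOP2A at 10.01 (89.9 to 185) and COX7A2 at 14907 (23658 to 30272) stood apart in 1 dpn animal 4. CENPF at 10.2 (109.5 to 138) stood apart in 1 dpn animal 5. PEG10 at 128 (1389 to 4808) stood apart in 1 dpn animal 6. PECAM1 at 4349 (2979 to 3433), ITIH3 at 9.32 (66.7 to 101) and MYOD1 at 1506 (843 to 953) stood apart in 28 dpn animal 1. The endothelial list at 551 (380.2 to 429), PEG3 at 34.8 (147 to 253), ATF4 at 41285 (22875 to 27176) and NANOS1 at 72.4 (149.8 to 216) stood apart in 28 dpn animal 2. RRM2 at 68.96 (166 to 199), POSTN at 418 (1408 to 2398) and CDO1 at 534 (915 to 1234) stood apart in 28 dpn animal 2. EGF at 1766 (3534 to 5041), MOSPD2 at 49.9 (133 to 174) and COX6A1 at 4913 (3766 to 4017) stood apart in 28 dpn animal 3. The amino acid catabolism list at 76.4 (115 to 144), CYP3A29 at 8.44 (165 to 358) and ARNTL at 6.48 (51.6 to 140.0) stood apart in 28 dpn animal 4. RPS25 at 16466 (18552 to 19540.4) stood apart in 28 dpn animal 5. PYGM at 39558 (48298 to 53725) and MYL1 at 57352 (70649 to 77620.4) stood apart in 188 dpn animal 2. SHTN1 at 7.60 (28.4 to 60.1) stood apart in 188 dpn animal 3. MYBL2 at 36.3 (4.89 to 6.66) stood apart in 188 dpn animal 4. HSPB7 at 1567 (2635 to 3386) stood apart in 188 dpn animal 5. The actin 5′ to 3′ ratio at 0.212 (0.145 to 0.166) and ARNTL at 79.7 (175 to 222) stood apart in 188 dpn animal 6.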

How the results depend on the processing

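The 2 alternatives that leave out 3 arrays were chosen after seeing the data. No paired analysis was possible, as the labels name no mother. Probe sets under the background of 74.7, 39.2% of those tested, have folds only as bounds. Of the values of named genes under alternatives other than leaving out 1 animal, 2344 kept direction and side of the threshold, 47 lost the call, 4 gained one and 3 reversed, and of those of lists 304 kept both, 79 lost the call and 7 reversed. With 1 animal left out, 4409 values of genes kept both, 30 lost the call and 1 gained one, and of lists 1028 kept both and 28 lost the call. Where no reason is given, the cause was not tested. An adjusted p of 0.01 left 4824, 2735 and 1856 probe sets in the first 3 comparisons and 1960 highest and 2149 lowest at 1 stage, as a stricter threshold must. Adding 64 before the log2 left 2591, 1451 and 971 with a 2-fold change in these comparisons. Fitting only 28 dpn and 1 dpn gave 3091. Testing 1 probe set per gene, which tests fewer, gave 2781, 2102, 1683 and 3602 changed and 1326, 811, 681 and 2143 with a 2-fold change. With an estimated correlation 4, 0, 1 and 3 lists were called, with fry's directional test 19 for 1 dpn with 94 dpc and 21 for 188 dpn with 94 dpc, and with its mixed test 30, 26, 28 and 32. Without the 3 arrays of low 5′ signal 3088 probe sets and 4 lists differed between 28 dpn and 1 dpn, and without the 3 arrays of ALB over 10000 2072 and 7 between 188 dpn and 28 dpn; both leave fewer arrays. Quantile normalization reversed MYL1 (-0.0737), RPS20 (-0.0305) and the ribosomal list (-0.15) for 1 dpn with 94 dpc, and the mean of all probe sets reversed B2M for 28 dpn with 1 dpn (0.35). Without the arrays of ALB over 10000 the xenobiotic metabolism (-0.26), plasma protein (-0.92), complement (-0.22), urea cycle (-0.49) and amino acid catabolism (-0.15) medians reversed for 188 dpn with 28 dpn, and that of amino acid catabolism (-0.0609) for 188 dpn with 94 dpc. Of calls as deposited, 73.9, 95.7, 68.6 and 73.1% were called again in their direction with quantile normalization and 71.0, 93.4, 63.2 and 69.5% with centred arrays. Leaving out 1 animal gave 6566 to 7475, 4265 to 5388, 2817 to 3703 and 8983 to 9741 changed probe sets and 4000 to 4692, 2333 to 3009, 1605 to 1874 and 6396 to 6783 with a 2-fold change. It gave 11839 to 12650 in the F test, 3048 to 3586 highest and 3439 to 4066 lowest at 1 stage, and 9 to 12, 6 to 8, 10 to 16 and 11 to 15 lists.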

Other observations

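The 10 lists of muscle biology in this part were chosen after the data were seen, so their counts are not independent evidence of a direction. Of the muscle glycogen and glycolysis list, 13 of 17 genes rose and 0 fell (14 and 0 within the list) from 94 dpc to 1 dpn (adjusted p = 8.97e-09; 0.135 with an estimated correlation). FBP2 rose from 717 to 7375 (3.36 ± 0.31) and the phosphofructokinase PFKM rose from 3916 to 16719 (2.09 ± 0.24). From 1 dpn to 28 dpn 11 of 17 genes rose and 0 fell (12 and 0 within the list) (adjusted p = 5.38e-09; 0.0671 with an estimated correlation), among them PHKB, of phosphorylase kinase, from 1978 to 8368 (2.08 ± 0.19) and AMPD1, the AMP deaminase of muscle, from 7394 to 31198 (2.08 ± 0.23). From 94 dpc to 188 dpn 16 of 17 genes rose and 0 fell (16 and 0 within the list) (adjusted p = 1.87e-13; 0.0173 with an estimated correlation), with PFKM from 3916 to 49734 (3.67 ± 0.24), PHKB from 1316 to 15439 (3.55 ± 0.19) and GPI from 4367 to 38917 (3.16 ± 0.19). Of the fast fibre list 9 of 9 genes rose and 0 fell (9 and 0 within the list) from 94 dpc to 188 dpn (adjusted p = 1.13e-05; 0.0971 with an estimated correlation). From 94 dpc to 1 dpn 6 of 9 genes rose and 0 fell (6 and 0 within the list) (adjusted p = 0.000592; 0.208 with an estimated correlation), a rise whose median turned to -0.01 with quantile normalization. Of slow fibre genes 6 of 9 genes rose and 2 fell (6 and 2 within the list) in that interval (adjusted p = 0.0289; 0.425 with an estimated correlation) and 7 of 9 genes rose and 2 fell (7 and 2 within the list) from 94 dpc to 188 dpn (adjusted p = 0.0222; 0.386 with an estimated correlation). With quantile normalization the slow fibre median went from 0.72 to 0.04 in the first of these intervals and from 0.99 to 0.44 in the longer one, the fast fibre median from 0.94 to 0.35 in the longer one, and the glycogen and glycolysis median from 1.17 to 0.66 in the first. Of calcium handling 4 of 5 genes rose and 1 fell (4 and 1 within the list) over the latter (adjusted p = 0.0171; 0.229 with an estimated correlation). Lists of adipocytes, of nerve and of myogenic regulators passed in no comparison, with lowest adjusted p of 0.367, 0.639 and 0.109.

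Genes of muscle loss rose in part late in the series. Of the atrophy list, 5 of 9 genes rose and 0 fell (5 and 0 within the list) from 28 dpn to 188 dpn (adjusted p = 6.70e-05; 0.0175 with an estimated correlation), and 5 of 9 genes rose and 0 fell (5 and 0 within the list) from 94 dpc to 188 dpn (adjusted p = 0.0144; 0.0971 with an estimated correlation). The transcription factor KLF15 rose from 330.4 to 1075 (1.70 ± 0.23) and SQSTM1, a receptor of autophagy, rose from 4744 to 12798 (1.43 ± 0.27). Of developmental sarcomere genes 0 of 8 genes rose and 4 fell (1 and 4 within the list) from 28 dpn to 188 dpn (adjusted p = 0.0186; 0.369 with an estimated correlation), among them the smooth muscle actin ACTA2 from 12773 to 5715 (-1.16 ± 0.15). From 94 dpc to 188 dpn TNNT2 fell from 3041 to 67.99 (at least 40.7-fold, SD 0.37 and 1.25), MYL4 fell from 6286 to 251 (-4.65 ± 0.29) and ACTC1 fell from 33342 to 1149 (-4.86 ± 0.29). Of the imprinted list 1 of 12 genes rose and 8 fell (2 and 10 within the list) from 94 dpc to 188 dpn (adjusted p = 0.00259; 0.0173 with an estimated correlation), and 0 of 12 genes rose and 6 fell (0 and 6 within the list) from 1 dpn to 28 dpn (adjusted p = 0.0298; 0.0671 with an estimated correlation).

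MSTN, which restrains muscle growth, and GHR, the growth hormone receptor, were lowest at 1 dpn and chosen after their values were seen. MSTN fell from 223 to 30.1 (at least 2.99-fold, SD 0.84 and 1.11) from 94 dpc to 1 dpn and rose from 30.1 to 175 (at least 2.34-fold, SD 1.11 and 0.69) by 28 dpn. GHR fell from 401 to 51.7 (at least 5.37-fold, SD 0.46 and 1.81) and rose from 51.7 to 407 (at least 5.45-fold, SD 1.81 and 0.23) over these intervals. The 4 calls held without the 3 arrays of 1 dpn with low 5′ signal. Over the alternatives adjusted p was 9.11e-08 to 0.00273 for MSTN and 5.73e-06 to 0.0106 for GHR in the first interval and 2.12e-06 to 0.00792 for MSTN and 1.24e-05 to 0.0161 for GHR in the second.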
